A study of Homo sapiens with 8 samples.

How the data were processed

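Poly(A) mRNA and ribosome nascent-chain complex-bound mRNA of A549 cells with a METTL1 or a GFP hairpin were sequenced, 2 libraries in each of 4 groups. Per the labels, RNA was extracted with TRIzol and libraries were made with a stranded TruSeq mRNA kit. The deposited table holds gene-level TPM for 19024 genes, made by the authors. The submitters' processing notes name TopHat2, HTSeq and hg38; their versions, and the tool that made the TPM, are not given in the sources used here. Of the listed IDs 18936 were protein-coding and 18996 matched GENCODE release 29, while 28 did not. The listed genes summed to between 853903 and 925433 TPM per library, so the scale was set over a wider list of features. Read counts were not used here, and depth and counting error are unknown. Symbols stored as dates were repaired for 12 genes, and 18 symbols belonged to a second ID.

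Genes with at least 1 TPM in at least 2 libraries were kept, which left 12169. Values were taken as log2(TPM + 1). limma 3.58.1 in R 4.3.3 fitted the 4 group means to all 8 libraries, with 4 residual degrees of freedom and an intensity trend in the moderated variance. The comparisons were shM1 with NC in input, shM1 with NC in RNC, the interaction of fraction and knockdown (the change of the RNC to input ratio), and RNC with input in NC. P-values were adjusted by Benjamini-Hochberg over all tested genes, and an adjusted p under 0.05 passed.

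Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with an estimated correlation and the fry rotation test as alternatives. Of 34 lists, 29 had 5 or more tested members. The others were not tested. Nuclear noncoding RNAs had 0 of 18 members in the table. Of the snoRNA host genes 1 was tested (TAF1D, mean 77.1 TPM), of leukocyte markers 3 (highest CD68, 51.3 TPM), of endothelial markers 2 (highest EGFL7, 89.7 TPM) and of red cell markers 2 (highest HBA1, 0.715 TPM). The ribosomal protein, mitochondrial and histone lists served as signs of RNA composition.

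Named genes were METTL1 and WDR4, then the 8 genes with the largest change per direction among those that passed with a mean of at least 5 TPM and no overlap between libraries. Where fewer than 8 passed, up to 4 with the smallest unadjusted p at that mean were named as not passing. From each list that passed, up to 4 members with the smallest p could be named. Some genes that meet this rule are not reported here. The comparisons, tests, lists, rule for named genes and first set of alternatives were fixed before the data were examined. CDKN2A, MAGEA4, AKR1C1, FN1, ACTA2, HIST2H2AA3, CCN1 and the genes shared by the fits to single fractions were chosen after their values were seen.

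This first set comprised other pseudocounts, filters, scalings and variance models, removal of mitochondrially encoded genes, fits to only the libraries compared, blocks by library number, and omission of each library in turn. For the RNC to input ratio, the fit to only the libraries compared used differences of libraries sharing a number, although the labels do not say that such libraries are paired. Where an omission left a group with 1 library, limma assumed that it varied like the other groups. After the data were seen, alternatives were added that removed a spline trend (4 degrees of freedom) on transcript length and GC content, known for 12120 tested genes (99.6%), or left out both shM1 libraries numbered 2. Others combined the trend with the omission of input NC 1, and the fits to only the libraries compared with scaling, trend or omissions.

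The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. With the spread of all 8 libraries limma found 0% of the 2-fold changes in input, RNC and the ratio, and 3%, 0% and 0% of the 4-fold changes. With the spread without input NC 1 it found 2%, 3% and 0%, and 35%, 51% and 4%. Libraries were drawn independently, and 8 were simulated at both spreads. Figures and tables were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.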

Results

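Gene expression and ribosome binding of mRNA were measured in A549 cells, a human lung adenocarcinoma line. The cells carried a stable short hairpin RNA against METTL1 (shM1) or, as control, a hairpin against GFP (NC). METTL1 is the catalytic subunit and WDR4 the partner subunit of the enzyme that places N7-methylguanosine on tRNAs. Total poly(A) mRNA (input) and mRNA bound to ribosome nascent-chain complexes (RNC) were sequenced, with 2 libraries in each of the 4 groups, in order to find genes whose translation differed after METTL1 knockdown. The deposited table gave TPM for 19024 genes, and 12169 of them entered the tests. The TPM of the listed genes summed to between 853903 and 925433 per library. The read depth behind them is unknown, so no counting error can be given. The labels do not say that the replicates came from separate cultures, so every limma p-value measures only the spread between these samples, which may be technical. Camera p-values at the preset correlation come from the spread across genes under that assumed correlation. They do not measure the spread between libraries or cultures. For a single value, 2 libraries against 2 cannot give a two-sided exact permutation p below 0.333. Fold changes on log2(TPM + 1) understate changes of genes at low levels. The median log2 change of all genes was −0.08 in input, −0.38 in RNC, −0.29 in the RNC to input ratio and 0.43 between RNC and input in control cells; after median-of-ratios scaling it was 0.02, 0.03, 0.01 and 0.01. List values are medians relative to all tested genes.

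The library labelled input NC 1 stood apart from the other 7, as shown by genes chosen after their values were seen. CDKN2A, a cell cycle inhibitor whose locus is deleted in A549, was listed at 285 TPM in it and at no more than 0.849 TPM in each of the others. MAGEA4, a cancer-testis antigen, was at 397 TPM against at most 0.423 TPM. AKR1C1, an aldo-keto reductase regulated by NRF2, was at 0.537 TPM against at least 917 TPM. Across genes, which are not independent replicates, its highest Pearson correlation with another library was 0.848, whereas the lowest among the other 7 was 0.884. The shM1 libraries numbered 2 also differed from the rest. Mitochondrially encoded genes took 2.86% of the listed TPM in the input and 1.19% in the RNC library of that number, against 4.3% to 13.8% in the other 6. Cytosolic ribosomal protein genes took 30.7% in the input library of that number, against 16.7% to 25.6% in the other input libraries, and 24.1% in the RNC library, against 14.3% to 16.8% in the other RNC libraries.

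METTL1 mRNA was lower in every knockdown library than in any control library of its fraction. The gene (ENSG00000037897.17) lies on chromosome 12 from 57768471 to 57772793 in GRCh38. It was measured at 47.3 and 57.6 TPM in input NC, 14.2 and 17.4 TPM in input shM1, 41.9 and 58.5 TPM in RNC NC, and 13.7 and 18 TPM in RNC shM1. The means were 52.4 ± 7.3 (SD, n = 2) and 15.8 ± 2.27 (SD, n = 2) TPM in input, or 30.1% of control, and 50.2 ± 11.7 (SD, n = 2) and 15.9 ± 3.0 (SD, n = 2) TPM in RNC, or 31.6% of control. The log2 fold change on the log2(TPM + 1) scale was −1.67 (SE 0.44, limma adjusted p = 0.404) in input and −1.59 (SE 0.44, limma adjusted p = 0.573) in RNC, neither passing over all genes in the fit to 8 libraries. The planned fit to the 4 RNC libraries alone gave every gene the common trend spread, so its p-values ignore each gene's own replicate spread. In that fit METTL1 passed (limma adjusted p = 0.0378). There its limma adjusted p was 0.0293 with length and GC trends removed and 0.21 after median-of-ratios scaling, and METTL1 did not pass without the shM1 library numbered 2. These combined settings were chosen after the data were seen. In the 4 input libraries alone it did not pass (limma adjusted p = 0.466). WDR4 (ENSG00000160193.11), on chromosome 21 from 42843094 to 42879568, was at 63.7% of control in input and 74.7% in RNC. Its log2 fold changes of −0.62 (SE 0.48, limma adjusted p = 0.714) and −0.36 (SE 0.48, limma adjusted p = 0.741) did not pass, and the latter turned to 0.10 after median-of-ratios scaling and to 0.06 after quantile normalization.

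**Figure D1:**
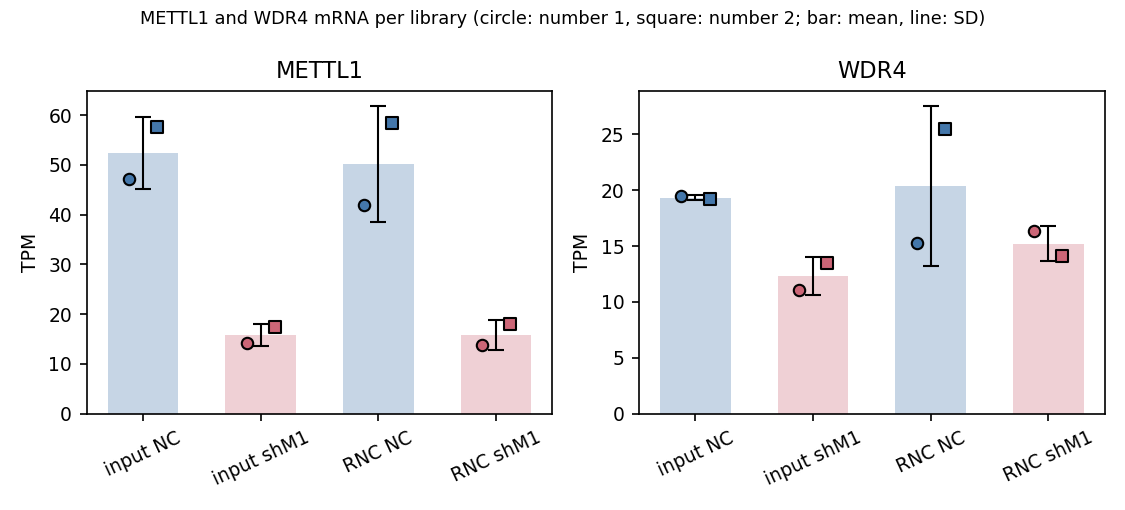
TPM of METTL1 (left) and WDR4 (right) in each library of the 4 groups, with bars at the group mean, lines for the SD and the library number shown by the symbol. All shM1 libraries lie at or below 18 TPM of METTL1, and all NC libraries at or above 41.9 TPM.

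In total mRNA, which shows transcript levels apart from translation, genes that drive cell division fell after knockdown relative to all tested genes. The DNA replication list (helicase, clamp loader and origin factors) had a median log2 fold change of −1.05 relative to all genes, with 46 of 49 members below the median of all genes (camera adjusted p = 2.5e-10; adjusted p = 0.796 with an estimated correlation). The G2/M and mitosis list was at −1.20, with 47 of 52 members below (camera adjusted p = 8.16e-09; adjusted p = 0.796 with an estimated correlation). The list of G1/S cyclins and CDKs was at −0.67, with 18 of 23 members below (camera adjusted p = 0.00116; adjusted p = 0.796 with an estimated correlation). FOXM1, the transcription factor of the mitotic program, was at 183 and 101 TPM in control and 40.4 and 12.8 TPM in knockdown libraries, a log2 fold change of −2.52 (SE 0.74). GINS2, a subunit of the replicative helicase, was at 31.9 and 37.3 TPM and then at 14 and 8.07 TPM, and CDC25A, a phosphatase that activates CDKs, at 15.3 and 6.13 TPM and then at 2.38 and 0.667 TPM. None of these genes passed over all genes in the fit to 8 libraries or to the 4 input libraries alone. Without input shM1 2, the library with the low mitochondrial share, the lists were at −0.63, −0.31 and −0.47 in the same order, and the G1/S list no longer passed, nor did it (−0.65) over genes with a mean of at least 10 TPM. Without both shM1 libraries numbered 2 the G2/M list did not pass. Without input NC 1 the G2/M list was at −0.61, and without input shM1 1 the G1/S list was at −1.01. Relative to each library's median, the mean G2/M level was 0.826 in both input NC 2 and input shM1 1. The fall in its mean level therefore came from input NC 1 (1.602) and input shM1 2 (−0.42).

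Several stress and epithelial programs rose in total mRNA relative to all genes. The list of ER chaperones and the unfolded protein response was at 0.71, with 31 of 33 members above the median of all genes (camera adjusted p = 2.98e-06; adjusted p = 0.665 with an estimated correlation). Interferon response genes were at 0.54, with 25 of 31 members above (camera adjusted p = 3.72e-05; adjusted p = 0.665 with an estimated correlation). Epithelial junction genes were at 0.93, with 22 of 24 above (camera adjusted p = 9.76e-08; adjusted p = 0.665 with an estimated correlation). Targets of p53 were at 0.90, with 25 of 30 above (camera adjusted p = 6.98e-06; adjusted p = 0.749 with an estimated correlation). HSP90B1, an ER chaperone, was at 90.5 and 120 TPM in control and 353 and 194 TPM in knockdown libraries. IFITM1, an interferon-induced antiviral membrane protein, was at 0.137 and 1.41 TPM in control and 8.81 and 43.9 TPM in knockdown libraries. TJP3, a tight junction scaffold, was at 1.84 and 5.31 TPM and then at 14.7 and 44.3 TPM. MDM2, the p53-induced ubiquitin ligase, had a log2 fold change of 1.45 (SE 0.47). These 4 genes did not pass over all genes in the fit to 8 libraries or to the 4 input libraries alone. The p53 and epithelial lists depended in size on input NC 1, without which they were at 0.37 and 0.55, and the epithelial list was at 1.71 without input NC 2.

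NRF2 targets and inflammatory NF-κB targets were also higher in the fit to 8 libraries, but this rested largely on input NC 1. Relative to the median of all genes in each library, the mean NF-κB level was 1.68 in input NC 2. That lay between the knockdown libraries (1.619 and 2.142), whereas input NC 1 was at −0.919. The NRF2 level in input NC 2 (4.602) was slightly below both knockdown libraries (4.816 and 4.897), and that in input NC 1 was much lower. NRF2 targets, antioxidant and detoxification genes, were at 1.16 with 31 of 32 members above the median of all genes (camera adjusted p = 3.92e-09; adjusted p = 0.796 with an estimated correlation). NF-κB targets were at 1.05 with 22 of 28 above (camera adjusted p = 3.25e-06; adjusted p = 0.796 with an estimated correlation). With input NC 1 left out the NRF2 list was at 0.40 and the NF-κB list at 0.22, where the latter did not pass, and with only the other 3 input libraries fitted neither did (camera adjusted p = 0.122 and 0.161). They were at 2.16 and 2.08 without input NC 2. AKR1B10, an NRF2-regulated reductase, was at 1.25 TPM in input NC 1, 1141 TPM in input NC 2, and 3808 and 2311 TPM in the knockdown libraries. CCL20, a chemokine, was at 0.259 and 11.4 TPM in control and 59.6 and 71.6 TPM in knockdown libraries.

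Another 6 lists passed in total mRNA. Cholesterol synthesis genes were at −0.62 (camera adjusted p = 0.000141; adjusted p = 0.796 with an estimated correlation), ribosome biogenesis at −0.29 (camera adjusted p = 0.0178; adjusted p = 0.796 with an estimated correlation) and tRNA modification at −0.27 (camera adjusted p = 0.0255; adjusted p = 0.818 with an estimated correlation). Glycolysis and hypoxia genes were at 0.18 (camera adjusted p = 0.0355; adjusted p = 0.796 with an estimated correlation), nuclear OXPHOS subunits at 0.23 (camera adjusted p = 0.0352; adjusted p = 0.818 with an estimated correlation) and the 5 tested alveolar and lung secretory genes at 0.54 (camera adjusted p = 0.0308; adjusted p = 0.665 with an estimated correlation). Without input NC 1, cholesterol synthesis (−0.20), ribosome biogenesis (−0.09), tRNA modification (−0.16) and alveolar genes (0.38) did not pass, whereas OXPHOS was at 0.39. Without input NC 2, cholesterol synthesis was at −1.03, alveolar genes (0.95), glycolysis (0.19), OXPHOS (0.08, with the test pointing lower) and tRNA modification (−0.25) did not pass. Without input shM1 2, ribosome biogenesis (−0.32), tRNA modification (−0.17), glycolysis (0.09), OXPHOS (−0.17) and alveolar genes (0.25) did not pass. Without input shM1 1, glycolysis (0.28) did not pass, OXPHOS was at 0.74 and alveolar genes were at 0.85, and OXPHOS did not pass without either RNC NC library (0.23). Median-of-ratios scaling ended the calls of OXPHOS (0.26), ribosome biogenesis (−0.26) and alveolar genes (0.53), and quantile normalization those of OXPHOS (0.20), ribosome biogenesis (−0.30), alveolar genes (0.46) and tRNA modification (−0.24). OXPHOS also did not pass with only the libraries compared (0.23), with the length and GC trend removed (0.10) or without mitochondrially encoded genes, as glycolysis did not in the last setting. With no filter on low values, glycolysis (0.13) and alveolar genes (median −0.03, with the test still pointing higher) did not pass. SCD, the desaturase that makes monounsaturated fatty acids, was at 431 and 149 TPM in control and 81.5 and 18.7 TPM in knockdown libraries.

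Among the lists that did not pass in total mRNA, camera adjusted p was 0.88 for other m7G methyltransferases and decay factors, 0.13 for translation factors, 0.479 for cytosolic aminoacyl-tRNA synthetases, 0.51 for ATF4 targets, 0.967 for mesenchymal matrix genes, 0.107 for growth factor, PI3K and mTOR signalling, and 0.88 for fibroblast markers. It was 0.873 for cytosolic ribosomal proteins, 0.352 for mitochondrially encoded genes, 0.144 for mitochondrial ribosomal proteins, 0.13 for replication-dependent histones, 0.88 for heat shock genes, 0.352 for proteasome subunits and 0.827 for KRAB zinc fingers. Some of these lists passed with 1 library left out. Ribosomal proteins passed as higher without input NC 1 (0.28) or input shM1 1 (0.79), but as lower without input shM1 2 (−0.57). Mitochondrial ribosomal proteins passed without input shM1 2 (−0.35), and histones (0.39) and ATF4 targets (−0.40) without input NC 1. Mitochondrially encoded genes passed without input shM1 1 (−1.51), and translation factors (−0.35) and proteasome subunits (−0.23) without input NC 2. Mitochondrial ribosomal proteins also passed with the length and GC trend removed (−0.26), and ATF4 targets without both shM1 libraries numbered 2 (−0.33). Over genes with a mean of at least 10 TPM, histones (0.72) and growth factor signalling (−0.22) passed. Median, mean and test direction differed in sign for other m7G factors (median 0.02, mean −0.10, lower), ribosomal proteins (0.12, −0.01, higher), ATF4 targets (−0.17, 0.01, lower) and heat shock genes (−0.08, 0.07, higher). Adjusted over the list alone, CCL20 and IL1B of the NF-κB list, CLDN2, TJP3 and ITGB4 of the epithelial list, MUC5B of the secretory list, HIST2H2AA3 of the histones, and FN1 and ACTA2 of the matrix list were higher, and CCN1 of the matrix list was lower. Over all genes none of them passed in the fit to 8 libraries. In the planned fit to the 4 input libraries alone CCL20 (limma adjusted p = 0.0434), CLDN2 (0.0222), MUC5B (0.0238) and CCN1 (0.0434) passed over all genes, but none of these after median-of-ratios scaling, with the length and GC trend removed or without input NC 1. HIST2H2AA3 is near-identical to HIST2H2AA4, so its value is uncertain.

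No single gene of the 12169 passed in total mRNA in limma, the smallest adjusted p being 0.127. At this spread the test found 3% of simulated 4-fold changes, so large changes could be missed. At an unadjusted p under 0.05, 652 genes were higher and 442 lower, with 608 expected by chance. Among genes with a mean of at least 5 TPM, the higher genes with the smallest p were APOH, a plasma glycoprotein (log2 fold change 4.63, SE 0.68), the ribonuclease RNASE4 (4.46, SE 0.65), the vitamin B12 carrier TCN1 (3.60, SE 0.53) and the scaffold USH1C (4.06, SE 0.61). Lower genes with a small p included the ubiquitin ligase MARCHF4 (−3.85, SE 0.66), the potassium channel KCNMA1 (−2.73, SE 0.54) and metallothionein MT2A (−2.08, SE 0.43). Without input NC 1, 0 genes passed in limma, with 209 higher and 124 lower at an unadjusted p under 0.05. The planned fit to the 4 input libraries alone called 28 genes higher, among them APOH, RNASE4, TCN1 and USH1C, and 1 lower, and 4 higher without input NC 1 (PIP, LCN2, FGL1 and APOH), but 0 after median-of-ratios scaling (630 higher and 244 lower at an unadjusted p under 0.05) and 0 after removal of length and GC trends (554 and 279). Without input NC 2, which leaves input NC 1 as the only input control, 610 genes were called higher and 239 lower. After quantile normalization the genes at an unadjusted p under 0.05 were 696 higher and 794 lower.

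**Figure D2:**
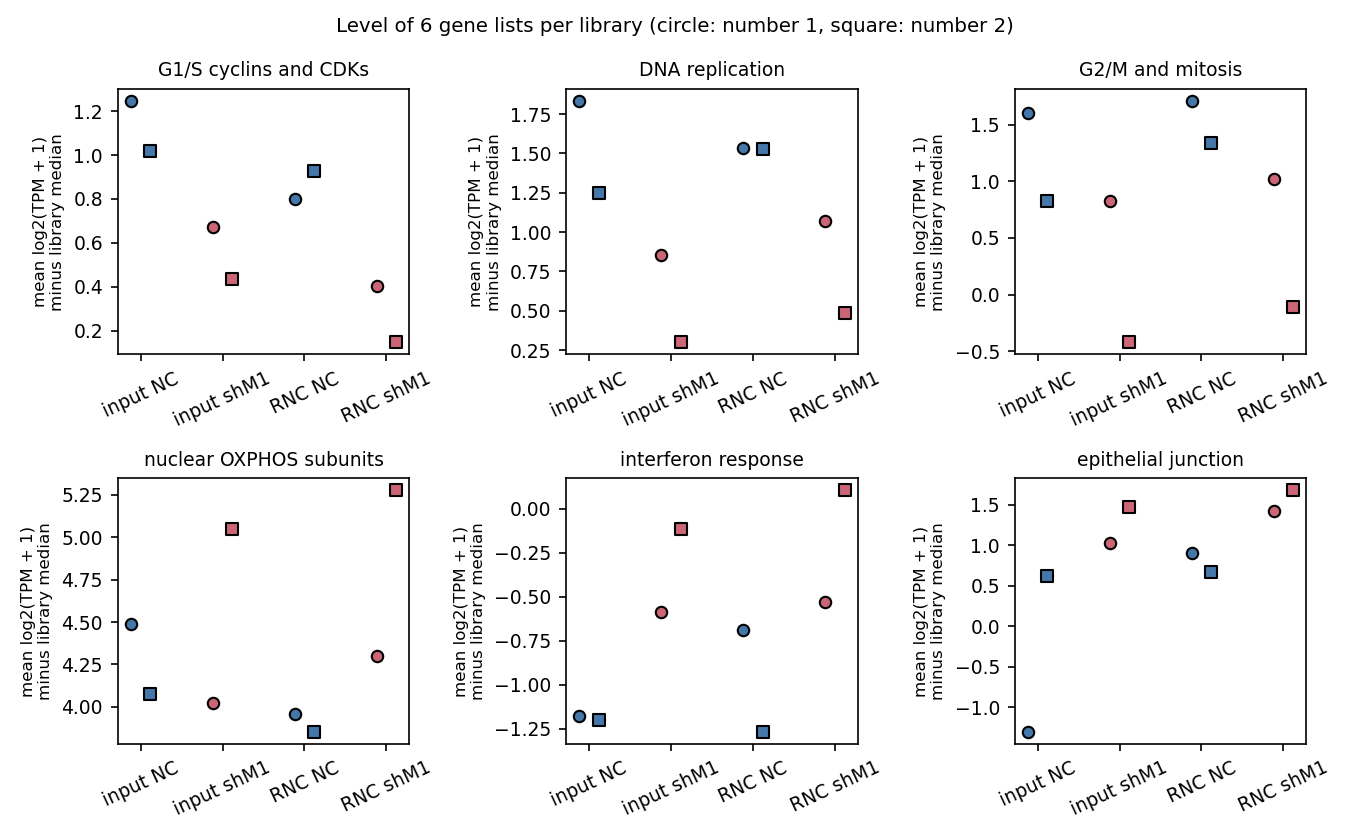
Mean log2(TPM + 1) of 6 gene lists minus the median of all tested genes in the same library, for each library of the 4 groups (circle, number 1; square, number 2). DNA replication was at 1.83 and 1.25 in input NC and at 0.86 and 0.30 in input shM1; in the OXPHOS panel the shM1 libraries numbered 2 lie above all others.

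In ribosome-bound mRNA, which shows what the cells were translating, cell division genes fell as well. The G2/M and mitosis list was at −1.27, with 52 of 52 members below the median of all genes (camera adjusted p = 7.13e-10; adjusted p = 0.791 with an estimated correlation). The DNA replication list was at −0.88, with 46 of 49 below (camera adjusted p = 9.67e-09; adjusted p = 0.791 with an estimated correlation), and G1/S cyclins and CDKs were at −0.68, with 21 of 23 below (camera adjusted p = 0.000136; adjusted p = 0.791 with an estimated correlation). BIRC5, the survivin gene, was at 69.1 and 91.8 TPM in control and 38.0 and 15.7 TPM in knockdown libraries. CDC6, a replication licensing factor, was at 50.9 and 80.7 TPM and then at 23.2 and 8.82 TPM. CCNA2, cyclin A2, had a log2 fold change of −2.38 (SE 0.83). These genes did not pass over all genes in the fit to 8 libraries. In the planned fit to the 4 RNC libraries alone, at the common trend spread, BIRC5 (limma adjusted p = 0.0146), CDC6 (0.00256) and CCNA2 (0.00177) passed. They did not pass after median-of-ratios scaling or without RNC shM1 2. Without RNC shM1 2, the library with 1.19% of its TPM on mitochondrial genes, the 3 lists were at −0.57, −0.48 and −0.35 in the same order and still passed, and without RNC shM1 1 the G2/M list was at −1.95 and the G1/S list at −1.04.

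Nuclear OXPHOS subunits, the proteins of the respiratory chain and ATP synthase, rose in RNC relative to all genes, with a median of 0.83 and 68 of 76 members above (camera adjusted p = 3.63e-14; adjusted p = 0.791 with an estimated correlation). Epithelial junction genes were at 0.61, with 18 of 24 above (camera adjusted p = 0.00285; adjusted p = 0.791 with an estimated correlation). ER chaperones were at 0.37, with 26 of 33 above (camera adjusted p = 0.00152; adjusted p = 0.791 with an estimated correlation). Interferon response genes were at 0.36, with 22 of 31 above (camera adjusted p = 0.00173; adjusted p = 0.791 with an estimated correlation). Of these lists the ER and interferon medians before subtraction were −0.01 and −0.02. COX6C, a cytochrome c oxidase subunit, was at 378 and 301 TPM in control and 508 and 763 TPM in knockdown libraries. ITGB4, the hemidesmosomal integrin chain, was at 55.0 and 46.4 TPM and then at 179 and 159 TPM. IFITM1 was at 3.96 and 0.446 TPM and then at 13.9 and 54.9 TPM. Neither COX6C, ITGB4 nor IFITM1 passed over all genes in the fit to 8 libraries. In the planned fit to the 4 RNC libraries alone, at the common trend spread, ITGB4 (limma adjusted p = 0.00352) and IFITM1 (6.92e-06) passed and COX6C (0.148) did not. After median-of-ratios scaling neither ITGB4 (limma adjusted p = 0.0666) nor IFITM1 (0.117) passed there, and IFITM1 (0.146) did not pass without RNC shM1 2. OXPHOS was at 0.52 with the length and GC trend removed and at 0.42 after quantile normalization, passing in both. Without RNC shM1 2 OXPHOS was at 0.41, and without RNC shM1 1 it was at 1.27, ER chaperones were at 0.63 and interferon genes at 0.56. Without RNC NC 2 interferon genes (0.04) did not pass and ER chaperones were at 0.56, and without RNC NC 1 interferon genes were at 0.61.

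Another 5 lists passed in RNC. Cytosolic ribosomal proteins were at 0.57 (camera adjusted p = 3.82e-06; adjusted p = 0.791 with an estimated correlation), replication-dependent histones at 0.34 (camera adjusted p = 0.007; adjusted p = 0.791 with an estimated correlation) and the 5 alveolar and secretory genes at 0.34 (camera adjusted p = 0.0336; adjusted p = 0.791 with an estimated correlation). tRNA modification genes were at −0.16 (camera adjusted p = 0.0279; adjusted p = 0.791 with an estimated correlation) and KRAB zinc fingers at −0.25 (camera adjusted p = 0.0415; adjusted p = 0.791 with an estimated correlation). Ribosomal protein genes, which took 24.1% of the TPM in RNC shM1 2, were at −0.08 without that library and did not pass, and at 1.22 without RNC shM1 1; after quantile normalization they were at 0.05 and the test pointed lower. Histones did not pass without RNC NC 2 (0.17) or RNC shM1 1 (0.23), and were at 0.74 without RNC NC 1 and 0.64 without RNC shM1 2. Alveolar genes did not pass without RNC NC 2 (0.19) or either input NC library (0.34), and were at 0.63 without RNC NC 1. tRNA modification did not pass without RNC NC 2 (−0.18) or RNC shM1 1 (−0.20) and was at −0.31 without RNC NC 1. KRAB zinc fingers did not pass without RNC NC 2 (−0.20), RNC shM1 1 (−0.23) or either input NC library (−0.25). Alveolar genes and tRNA modification did not pass after median-of-ratios scaling (0.33 and −0.16) or quantile normalization (0.46 and −0.13), nor did KRAB zinc fingers after quantile normalization (−0.17). With only the libraries compared tRNA modification (−0.16) and KRAB zinc fingers (−0.25) did not pass. With the length and GC trend removed ribosomal proteins (0.21), histones (0.01), alveolar genes (0.14) and KRAB zinc fingers (−0.01) did not pass. With a pseudocount of 0.1 alveolar genes (0.36) and KRAB zinc fingers (−0.43) did not pass, nor did histones without a filter on low values (0.02) or tRNA modification over genes with a mean of at least 10 TPM (−0.14). Of the other 17 lists none passed, with camera adjusted p from 0.0591 for NF-κB targets to 0.738 for translation factors. It was 0.0896 for NRF2 targets and 0.572 for p53 targets (camera adjusted p). Several of the 17 passed with 1 RNC library left out. These were ATF4 targets without RNC NC 1 (−0.36) or RNC shM1 2 (−0.27), matrix genes without RNC NC 2 (−0.57) or RNC shM1 2 (−0.28) and ribosome biogenesis without RNC shM1 2 (−0.17). Glycolysis passed without RNC NC 1 (0.49) and NF-κB targets without RNC NC 2 (0.67), while mitochondrial ribosomal proteins (0.56), proteasome subunits (0.62) and mitochondrially encoded genes (−1.66) passed without RNC shM1 1. Leaving out an input library, which changes only the spread, let matrix genes (−0.34) and NRF2 targets (0.48) pass without either NC library. The same omission of either shM1 library let NF-κB targets (0.40), mitochondrial ribosomal proteins (0.31) and mitochondrially encoded genes (−0.88) pass. After median-of-ratios scaling mitochondrial ribosomal proteins (0.37) and proteasome subunits (0.43) passed. After quantile normalization ATF4 targets (−0.25), heat shock genes (−0.30), mitochondrially encoded genes (−1.32) and ribosome biogenesis (−0.13) passed. With the length and GC trend removed ATF4 targets (−0.39) and NF-κB targets (0.27) passed, and with only the libraries compared matrix (−0.34) and mitochondrially encoded genes (−0.88). A block by number let NF-κB targets and mitochondrial ribosomal proteins pass, no filter on low values ATF4 targets, matrix genes and ribosome biogenesis, and a mean of at least 10 TPM ATF4 targets. Median and mean differed in sign for ribosome biogenesis (0.02 and −0.15) and heat shock genes (0.04 and −0.03), both tested as lower. Adjusted over the list alone, MUC5B of the secretory list was higher.

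No single gene passed in RNC in limma in the fit to 8 libraries, the smallest adjusted p being 0.447. At this spread the test found 0% of simulated 4-fold changes, so large changes could be missed. At an unadjusted p under 0.05, 249 genes were higher and 701 lower as deposited, 490 and 401 after median-of-ratios scaling, and 532 and 526 after quantile normalization. The lean to lower values rested largely on RNC shM1 2. The median log2 change of all genes in RNC was −0.092 without it and −0.685 without RNC shM1 1. Lower genes with a small p included GTF2H2C (log2 fold change −3.06, SE 0.60), which has a near-identical copy and is uncertain, the centromere protein CENPK (−3.12, SE 0.65) and the mitochondrial transcription factor TFAM (−3.19, SE 0.75). On the higher side were PRODH2 (3.44, SE 0.54), the adhesion molecule CEACAM1 (3.01, SE 0.50), TCN1 (3, SE 0.53) and USH1C (3.15, SE 0.61). Without a filter on low values 2 genes passed, both lower. The planned fit to the 4 RNC libraries alone called 182 genes higher and 425 lower, among them the 7 genes from GTF2H2C to USH1C above, with the lower ones including 30 of 52 G2/M genes, 13 of 49 DNA replication genes and 5 of 23 G1/S genes. That fit gave every gene the common trend spread, and the count rested on the scaling and on RNC shM1 2. It was 15 higher and 3 lower after median-of-ratios scaling, 102 higher and 168 lower with length and GC trends removed, and 45 higher and 13 lower without the shM1 library numbered 2. No member of the 3 proliferation lists was called after median-of-ratios scaling or without that library.

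Changes in RNC and in input went together across the 12169 genes (Pearson r = 0.529, and 0.637 without input NC 1), genes not being independent replicates. The fits to the input libraries alone and to the RNC libraries alone shared 25 higher genes and 1 lower gene, CCN1. These fits have no library in common, but they are not independent: across genes, the difference between the libraries numbered 1 and 2 of input shM1 correlated with that of RNC shM1 (Pearson r = 0.763). Whether same-numbered input and RNC libraries came from the same culture is not stated in the labels.

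The change of the RNC to input ratio, the measure of translation the study was designed for, showed no gene that passed. limma gave 0 calls in the interaction of fraction and knockdown, with a smallest adjusted p of 0.999. In simulated data this test found 0% of 4-fold changes at the spread of all 8 libraries and 4% at the spread without input NC 1. The simulated libraries were drawn independently, so these shares do not reflect the variation that same-numbered shM1 libraries had in common. The lack of calls therefore does not show that translation was unchanged. At an unadjusted p under 0.05, 11 genes were higher and 59 lower as deposited, 29 and 57 after median-of-ratios scaling, and 47 and 50 after quantile normalization, where chance gives 608. limma on the RNC minus input differences of same-numbered libraries also called 0 genes, with 43 higher and 1091 lower at that p. In the fit to 8 libraries less input NC 1, limma called 0 genes, with 10 higher and 18 lower. Without input NC 2, 42 genes were called higher and 277 lower, with input NC 1 as the only input control. The lean of the ratio to lower values moved when 1 library of a same-numbered shM1 pair was left out. Such an omission unbalances RNC against input. The median change over all genes was −0.534 without input shM1 2 and −0.583 without RNC shM1 1. It was −0.049 without input shM1 1 and −0.025 without RNC shM1 2. With both shM1 libraries numbered 2 left out it was −0.257, against −0.286 in the fit to 8 libraries. METTL1 itself had a log2 change of 0.08 (SE 0.62). Among higher genes with a mean of at least 5 TPM, the smallest p belonged to SMARCB1, a chromatin remodelling subunit (1.93, SE 0.75), ZNF814 (2.20, SE 0.99), the decapping enzyme DXO (1.55, SE 0.71) and C6orf136 (1.69, SE 0.84). Among lower genes at that mean it belonged to the collagen-modifying enzyme PLOD2 (−3, SE 1.01), the complement regulator CD46 (−2.21, SE 0.78), integrin ITGB1 (−1.98, SE 0.76) and COL4A5 (−2.39, SE 0.93).

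By gene list, the RNC to input ratio rose relative to all genes for 5 lists. OXPHOS subunits were at 0.54, with 65 of 76 members above the median of all genes (camera adjusted p = 1.32e-06; adjusted p = 0.898 with an estimated correlation). Cytosolic ribosomal proteins were at 0.48, with 68 of 75 above (camera adjusted p = 2.43e-05; adjusted p = 0.898 with an estimated correlation). Mitochondrial ribosomal proteins were at 0.40 (camera adjusted p = 0.000323; adjusted p = 0.898 with an estimated correlation), proteasome subunits at 0.51 (camera adjusted p = 0.00384; adjusted p = 0.898 with an estimated correlation) and cholesterol synthesis genes at 0.41 (camera adjusted p = 0.00505; adjusted p = 0.898 with an estimated correlation). With the length and GC trend removed OXPHOS was at 0.34, ribosomal proteins at 0.24 and mitochondrial ribosomal proteins at 0.26, all passing. None of the 5 passed after quantile normalization, where OXPHOS was at 0.24, ribosomal proteins at 0.09, mitochondrial ribosomal proteins at 0.11, proteasome subunits at 0.13 and cholesterol synthesis at 0.26, and cholesterol synthesis (0.21) did not pass without a filter on low values. Of the 5 only OXPHOS (0.35) passed without input NC 1, where ribosomal proteins were at 0.21, mitochondrial ribosomal proteins at 0.27, proteasome subunits at 0.15 and cholesterol synthesis at 0.11. Without input shM1 1, OXPHOS (0.10) and mitochondrial ribosomal proteins (0.07) did not pass, ribosomal proteins passed in the other direction at −0.19 and proteasome subunits were at 0.22. Without RNC shM1 2, OXPHOS (0.18), mitochondrial ribosomal proteins (0.14), ribosomal proteins (−0.16) and proteasome subunits (0.28) did not pass, and cholesterol synthesis was at 0.71. Without input shM1 2, OXPHOS was at 0.98, ribosomal proteins at 1.12 and mitochondrial ribosomal proteins at 0.69, while cholesterol synthesis (0.29) did not pass. Without RNC shM1 1 the values were 0.94, 1.15, 0.65 and 0.18 in that order, the last not passing, and without input NC 2 cholesterol synthesis was at 0.90. Proteasome subunits (0.48) did not pass without both shM1 libraries numbered 2. ATP5F1D, an ATP synthase subunit, had a log2 change of 1.16 (SE 0.78) and PSMB2, a proteasome subunit, of 0.93 (SE 0.58), and neither passed over all genes.

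The ratio fell for 4 lists, all of which lost the call without input NC 1. NRF2 targets were at −1.15 (camera adjusted p = 4.06e-06; adjusted p = 0.898 with an estimated correlation) and at 0.08 without that library. NF-κB targets were at −0.92 (camera adjusted p = 0.00218; adjusted p = 0.898 with an estimated correlation) and at 0.07 without it. Epithelial junction genes were at −0.65 (camera adjusted p = 0.0083; adjusted p = 0.898 with an estimated correlation) and at 0.12 without it. Targets of p53 were at −0.80 (camera adjusted p = 3.22e-05; adjusted p = 0.898 with an estimated correlation) and at −0.29 without it. Without input NC 2 the first 3 were at −2.28, −1.77 and −1.27. NF-κB targets also did not pass without input shM1 2 (−0.90), RNC NC 2 (−0.71) or RNC shM1 1 (−0.96), nor did epithelial genes without input shM1 2 (−0.78) or RNC shM1 1 (−0.66), and neither list passed without both shM1 libraries numbered 2, where epithelial genes were at −0.74. Epithelial genes (−0.65) also did not pass with genotype and number as a block (camera adjusted p = 0.0591) or in the fit to differences of same-numbered libraries (camera adjusted p = 0.0609). SLC7A11, the cystine transporter, was at 0.266 and 7.2 TPM in input NC, 19 and 5.73 TPM in input shM1, 26.7 and 21.3 TPM in RNC NC, and 20.1 and 9.77 TPM in RNC shM1. CXCL8, the interleukin 8 gene, was at 0.48 and 96.0 TPM in input NC, and its log2 change of −3.95 (SE 1.97) became −0.94 without input NC 1. Without input shM1 1, 14 lists passed. Of the other 20 lists none passed, with camera adjusted p from 0.0547 for aminoacyl-tRNA synthetases to 0.936 for G2/M genes, whose median of −0.19 and mean of −0.12 were lower while the test pointed higher. G1/S cyclins and CDKs were at −0.01 (camera adjusted p = 0.689). Of these 20 lists none passed without input NC 1, but several did without another library. G2/M genes passed as lower without RNC shM1 1 (−0.73) or input shM1 2 (−1.02). They passed as higher without RNC shM1 2 (0.49) or input shM1 1 (0.59), where DNA replication passed too (0.51 and 0.54). The mean G2/M level was 0.826 and −0.42 in input shM1 1 and 2, and 1.022 and −0.11 in RNC shM1 1 and 2. Each of these omissions splits a same-numbered pair and unbalances RNC against input, so the opposite signs do not show a change of translation. Aminoacyl-tRNA synthetases and translation factors passed as higher without RNC NC 1 (0.41 and 0.24), RNC shM1 1 (0.57 and 0.49), input NC 2 (0.75 and 0.47) or input shM1 1 (0.32 and 0.20). ER chaperones passed as lower without RNC NC 1 (−0.20), RNC shM1 2 (−0.42) or input shM1 1 (−0.41), and interferon genes without RNC NC 2 (−0.55) or RNC shM1 2 (−0.33). Lower calls also came for matrix genes without RNC NC 2 (−0.39) or input shM1 1 (−0.51), ATF4 targets without input NC 2 (−0.15) or input shM1 1 (−0.42), glycolysis without RNC NC 2 (−0.31) and mitochondrially encoded genes without RNC shM1 1 (−1.51) or input shM1 2 (−1.79). Histones passed as higher without RNC NC 1 (0.51). With the length and GC trend removed aminoacyl-tRNA synthetases (0.39), translation factors (0.32), matrix genes (−0.40) and glycolysis (−0.21) passed. Aminoacyl-tRNA synthetases passed after median-of-ratios scaling (0.26) or with a pseudocount of 0.1, and ER chaperones (−0.30) and heat shock genes (−0.33) after quantile normalization. Matrix, fibroblast and interferon genes passed as lower without a filter on low values. Mitochondrially encoded genes passed with genotype and number as a block or in differences of same-numbered libraries (−0.72), and without both shM1 libraries numbered 2 (−0.98). Heat shock genes had a median of 0.06 and a mean of −0.10, tested as lower. Adjusted over the list alone, no gene of any list passed.

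In control cells, the RNC and input fractions were compared to see which mRNAs were more or less abundant among ribosome-bound mRNA. Cytosolic ribosomal protein genes were lower in RNC, with a median of −0.77 relative to all genes and 74 of 75 members below (camera adjusted p = 1.25e-15; adjusted p = 0.904 with an estimated correlation). RPLP0, the ribosomal stalk protein, was at 4399 and 3767 TPM in input and 1994 and 2137 TPM in RNC. ER chaperones were higher in RNC, at 0.47 with 27 of 33 above (camera adjusted p = 0.00159; adjusted p = 0.904 with an estimated correlation), as were heat shock genes, at 0.47 with 23 of 27 above (camera adjusted p = 0.000544; adjusted p = 0.904 with an estimated correlation). HSP90AA1, the inducible cytosolic HSP90, was at 219 and 206 TPM in input and 1005 and 896 TPM in RNC. Proteasome subunits were at 0.10 (camera adjusted p = 0.045; adjusted p = 0.904 with an estimated correlation) and glycolysis and hypoxia genes at 0.27 (camera adjusted p = 0.0138; adjusted p = 0.904 with an estimated correlation). Mitochondrially encoded genes, translated on mitochondrial ribosomes, were at −0.98 (camera adjusted p = 0.0174; adjusted p = 0.904 with an estimated correlation) and turned to 0.18 after quantile normalization. Replication-dependent histones, whose mRNAs lack poly(A) tails, were at −0.56 (camera adjusted p = 0.0378; adjusted p = 0.904 with an estimated correlation). Proteasome (0.02), glycolysis (0.20), mitochondrially encoded (−1.07) and histone (−0.51) lists did not pass after median-of-ratios scaling. Proteasome subunits (0.10) also did not pass with number, or genotype and number, as a block or without an intensity trend in the variance, nor with a pseudocount of 5 (0.24) or without mitochondrially encoded genes. With only the libraries compared neither proteasome subunits (0.10) nor glycolysis (0.27) passed. Histones did not pass with the length and GC trend removed (−0.43), over genes with a mean of at least 10 TPM (−0.55) or with no filter on low values (−0.28), nor did mitochondrially encoded genes with no filter (−0.70).

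The lists of NRF2 targets at 1.19 (camera adjusted p = 2.17e-06; adjusted p = 0.904 with an estimated correlation), p53 targets at 0.70 (camera adjusted p = 0.00176; adjusted p = 0.904 with an estimated correlation) and epithelial junction genes at 0.85 (camera adjusted p = 0.000423; adjusted p = 0.904 with an estimated correlation) were also higher in RNC. With input NC 1 left out they were at 0.27, 0.23 and 0.30 and did not pass, and without input NC 2 they were at 2.14, 1.15 and 1.63. Histones did not pass without input NC 1 (−0.18), input NC 2 (−0.68) or RNC NC 2 (−0.34). Without input NC 1 ribosomal proteins were at −0.42, ER chaperones at 0.15, heat shock genes at 0.76 and proteasome subunits at 0.42, all passing. Without input NC 2, heat shock genes (0.20), proteasome subunits (−0.20), glycolysis (0.15) and mitochondrially encoded genes (−0.82) did not pass. Glycolysis was at 0.12 without RNC NC 1, not passing, and at 0.41 without RNC NC 2. Proteasome subunits did not pass without RNC NC 1 (−0.03) or any 1 of the 4 shM1 libraries (0.10), and were at 0.20 without RNC NC 2. Of the other 19 lists none passed, with camera adjusted p from 0.0614 for cholesterol synthesis to 0.857 for translation factors. With input NC 1 left out, 8 of the 19 passed. G2/M genes were then at 0.80, aminoacyl-tRNA synthetases at 0.46, ribosome biogenesis at 0.44, interferon genes at 0.39, DNA replication at 0.36, matrix genes at 0.35 and translation factors at 0.31, while NF-κB targets went from 0.69 to −0.38. NF-κB targets passed as higher without input NC 2 (1.59) or RNC NC 1 (1.07), and OXPHOS as lower (−0.35 and −0.28). Cholesterol synthesis passed as lower without input NC 2 (−0.74) or RNC NC 2 (−0.40), and matrix (0.61) and interferon genes (0.61) as higher without RNC NC 2. After median-of-ratios scaling OXPHOS (−0.32), cholesterol synthesis (−0.43) and interferon genes (0.46) passed. After quantile normalization G2/M genes (0.31), NF-κB targets (0.53), aminoacyl-tRNA synthetases (0.39) and ribosome biogenesis (0.14) passed. Without mitochondrially encoded genes NF-κB, interferon and OXPHOS genes passed, and with no filter on low values NF-κB targets, interferon genes, aminoacyl-tRNA synthetases and ribosome biogenesis. Ribosome biogenesis passed with the length and GC trend removed (0.14), G2/M genes with genotype and number as a block, and aminoacyl-tRNA synthetases over genes with a mean of at least 10 TPM. In the fit to all 8 libraries, tRNA modification had a median of −0.04 and a mean of −0.01 while the test pointed higher. Adjusted over the list alone, EIF5B of the translation factors, HSP90B1 of the ER chaperones, and HSP90AA1, DNAJA1 and HSPH1 of the heat shock list were higher, and no gene of the other lists passed.

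No single gene passed between the fractions in limma, the smallest adjusted p being 0.393. At an unadjusted p under 0.05, 1427 genes were higher and 80 lower in RNC as deposited, 584 and 455 after median-of-ratios scaling, and 594 and 628 after quantile normalization. At a mean of at least 5 TPM, higher genes with a small p were the golgin GOLGA4 (log2 fold change 2.81, SE 0.55), PUM3 (2.57, SE 0.51) and MPHOSPH10 (2.59, SE 0.55), both of ribosome biogenesis, and EIF5B (2.66, SE 0.56). EIF5B, a GTPase of ribosomal subunit joining, was at 8.16 and 8.41 TPM in input and 76.2 and 43.6 TPM in RNC. On the lower side were ST6GALNAC4 (−1.88, SE 0.49), the histone mRNA processing protein LSM10 (−1.53, SE 0.43), SMIM29 (−1.37, SE 0.44) and C8orf88 (−2.11, SE 0.70). limma on the 4 NC libraries alone called 0 genes, with 2142 higher and 71 lower at an unadjusted p under 0.05. With input NC 1 left out, 2 genes were called lower, MTRNR2L11 and MTRNR2L10, which are nuclear copies of mitochondrial rRNA sequence and can share reads with it. Without input NC 2, 718 genes were called higher and 116 lower.

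**Figure D3:**
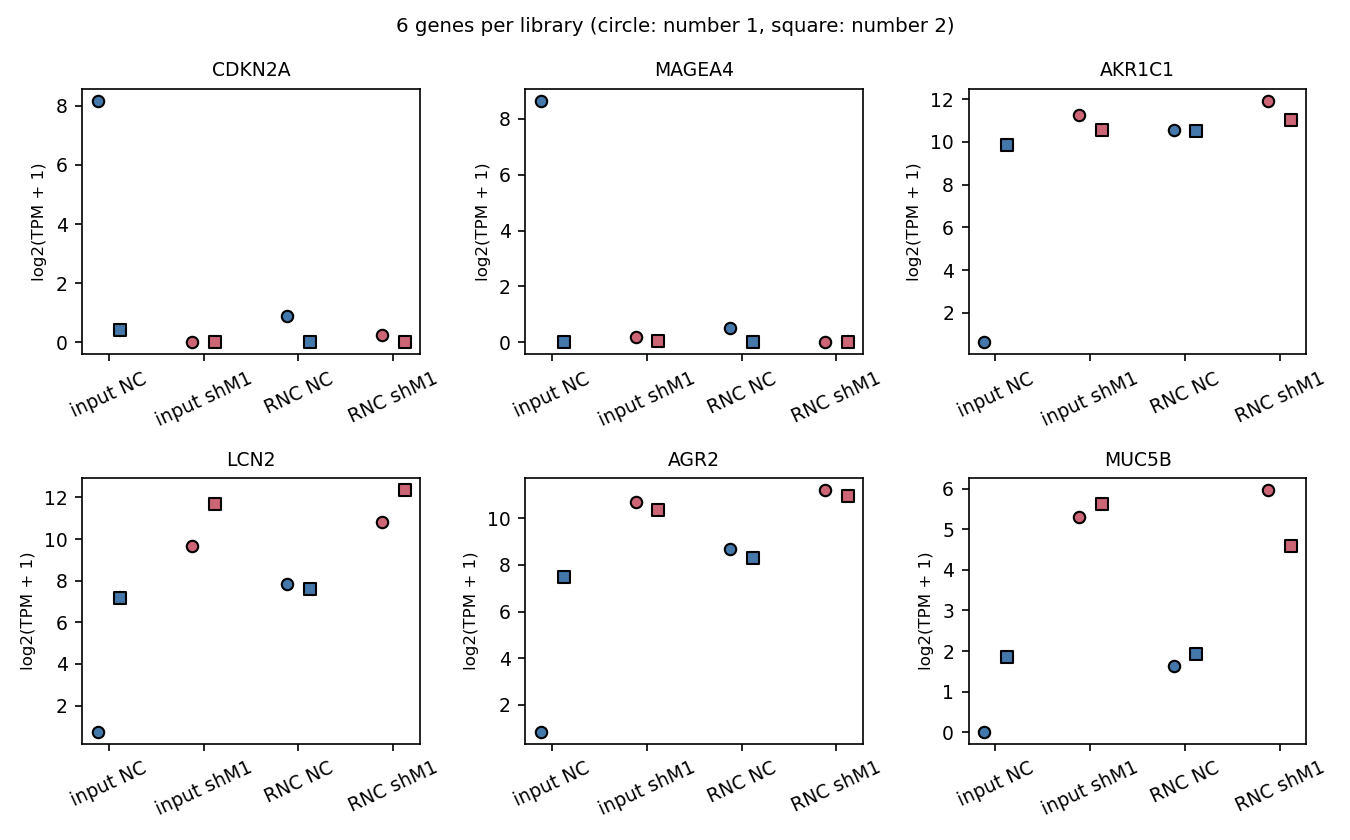
Log2(TPM + 1) of 6 genes in each library of the 4 groups (circle, number 1; square, number 2), chosen after their values were seen. CDKN2A and MAGEA4 are high, and AKR1C1 low, in input NC 1 alone; LCN2, AGR2 and MUC5B are higher in both shM1 libraries than in both NC libraries of each fraction.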

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

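The tests on input NC 1, including its omission from the other patterns, were chosen after the results were seen, as were the settings that removed the length and GC trend or left out both shM1 libraries numbered 2.

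In the test of the difference between fractions, the knockdown effect in RNC differed from that in input for 9 gene lists (camera at a preset correlation). With an estimated correlation none of these calls held (adjusted p = 0.898 for each), and fry called none. The median difference relative to all genes was 0.48 for cytosolic ribosomal proteins, 0.54 for nuclear OXPHOS subunits, 0.40 for mitochondrial ribosomal proteins, 0.41 for cholesterol synthesis and 0.51 for proteasome subunits. It was −0.80 for p53 targets, −1.15 for NRF2 targets, −0.92 for NF-κB targets and −0.65 for epithelial junction genes.

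The splits of the libraries into 2 and 2 were too few for a share under 0.05; 9 lists were called as labelled and up to 12 in the other splits of the ratio. Of the 4 lists that fell, 0 were called without input NC 1, so that library may account for their calls. With the length and GC trend removed over all 8 libraries, 9 of the 9 were called in the same direction. OXPHOS went from 0.54 to 0.34 and ribosomal proteins from 0.48 to 0.24. That setting kept input NC 1, so it cannot decide on the trend for lists whose calls may rest on that library. None of the 5 that rose was called after quantile normalization. Without input shM1 1 ribosomal proteins were at −0.19 and OXPHOS at 0.10, and without RNC shM1 2 they were at −0.16 and 0.18. These omissions split the same-numbered shM1 pairs and so unbalance RNC against input. Relative to each library's median, the mean OXPHOS level was higher in RNC (4.302 and 5.277) than in input (4.025 and 5.047) for shM1 1 and 2. For NC 1 and 2 it was lower in RNC (3.956 and 3.854) than in input (4.491 and 4.078). Ribosomal proteins were lower in RNC in every such pair. The omissions cannot show whether a single shM1 library was the cause, which remains open for these lists. Of these 5, 1 was called without input NC 1 (OXPHOS, 0.35), so that library remains open for the others. Without it and with the trend removed, OXPHOS was at 0.20 (camera adjusted p = 0.179) and 1 of the 9 was called in the same direction (p53 targets), so with 1 input control left the trend cannot be told apart from a change in translation for OXPHOS.

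The library labelled input NC 1 differed from the other 7. It held 285 TPM of CDKN2A, a gene deleted in A549, which is consistent with RNA of another cell line in that library. A mixture of A549 with other cells would keep a share of abundant A549 transcripts, but 34 genes with at least 100 TPM in each of the other 7 libraries were below 1% of their lowest level there. A swap within the series would need a partner out of place, but its highest correlation with another library (0.848) was below the lowest among the other 7 (0.884). No biological explanation within the design was tested, and an outside sample or wrong label remains open.

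The cell division lists (G1/S, DNA replication and G2/M) were lower after knockdown in both input and RNC in camera at a preset correlation. With an estimated correlation none was called (adjusted p = 0.796 for each in input and 0.791 for each in RNC), and fry called none. At the preset correlation, of these 6 list tests, 6 were called lower with the length and GC trend removed and 5 without both shM1 libraries numbered 2. With the trend removed G2/M, which moved most, was at −1.18 in input and −1.08 in RNC, which argues against the trend as the whole cause. Without both shM1 libraries numbered 2, G2/M was at −0.31 in input, so these libraries stay open as the cause there. The other 5 tests were then at −0.63 to −0.35. That argues against these libraries as the whole cause for them, though it rests on 1 shM1 library per fraction. All 6 were also called without input NC 1, but the RNC comparison does not hold that library, so only the input tests bear on it. Without input NC 1 they were at −0.54 (G1/S), −0.75 (DNA replication) and −0.61 (G2/M). For G1/S and DNA replication this argues against that library as the whole cause in input. The mean G2/M level was 0.826 in both input NC 2 and input shM1 1. Its fall without input NC 1 therefore rested on input shM1 2 and cannot decide the question for G2/M. The size depended on the shM1 libraries numbered 2: the G2/M list went from −1.20 to −0.31 in input without input shM1 2, and from −1.27 to −0.57 in RNC without RNC shM1 2. The splits were too few for a share under 0.05, with 14 lists called in the input libraries as labelled and up to 13 otherwise, and 12 and up to 15 in RNC. Slower division after loss of METTL1 may be the cause, but a difference between the cultures in growth or density was not recorded and stays open. All knockdown libraries carried the same label, shM1, so an effect of the hairpin or of the cell line made with it cannot be told apart from loss of METTL1.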

How the results depend on the processing

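The settings that remove the length and GC trend, leave out both shM1 libraries numbered 2, or combine choices were chosen after the data were seen. Among the alternatives set beforehand 4430 gene values and 772 list values kept their direction and side of the threshold, and 147 counts stayed similar in size. For genes this means that they still did not pass, as no gene passed in the fits to 8 libraries. Another 127 gene values newly passed, 198 list values no longer passed, 19 gene and 11 list values reversed, and 17 counts moved. Among added ones the numbers were 1143, 175 and 32, then 58, 50, 24, 9 and 6. Apart from the estimated correlation and fry, which called 0 lists in all 4 comparisons, the lists called in every alternative tried were DNA replication (−1.46 to −0.63), ER chaperones (0.52 to 1.04), p53 targets (0.37 to 1.26), interferon response (0.32 to 0.77) and epithelial junction (0.53 to 2.35) in input. In RNC they were G1/S (−1.04 to −0.35), DNA replication (−1.23 to −0.48), G2/M (−1.95 to −0.57), ER chaperones (0.20 to 0.63), OXPHOS (0.41 to 1.27) and epithelial junction (0.26 to 0.79). Between fractions in control cells they were cytosolic ribosomal proteins (−1.01 to −0.29) and ER chaperones (0.15 to 0.71). With library number as a block limma called 0 genes in all 4 comparisons, with 829 higher and 764 lower in input, 370 and 1425 in RNC, 16 and 142 in the ratio and 2094 and 109 between fractions at an unadjusted p under 0.05. Depth is unknown, so its limits cannot be given. For the changes that follow the cause was not tested.

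Without a filter on low values 2 genes were called in RNC. After median-of-ratios scaling WDR4 was at 0.10 in RNC and −0.45 between fractions, and ABCA3 at 0.35 in RNC; the RNC values were the same with only the libraries compared. After quantile normalization WDR4 was at 0.061 and ABCA3 at 0.42 in RNC, WDR4 at −0.48 between fractions, the ribosomal protein list at 0.046 in RNC with a test pointing lower and the mitochondrially encoded list at 0.18 between fractions. Without mitochondrially encoded genes WDR4 was at −0.12 between fractions. With only the libraries compared 29 genes were called in input and 607 in RNC, where METTL1 (−1.59) newly passed. In that fit of RNC, limma gave every gene the common trend spread; in simulated data with each gene's own residual spread it found 0% of 4-fold changes, and 67% with the common spread. With scaling added 18 genes were called in RNC, with the trend removed 270 (METTL1 at −1.86), and without both shM1 libraries numbered 2, 58; without input NC 1, 4 were called in input.

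Leaving out each library in turn gave 0 to 849 genes called in input, 0 in RNC, 0 to 319 in the ratio and 0 to 834 between fractions, and 11 to 16, 9 to 15, 1 to 14 and 8 to 14 lists. METTL1 ranged from −1.81 to −1.53 in input, −1.83 to −1.36 in RNC, −0.16 to 0.31 in the ratio and −0.31 to 0.16 between fractions. WDR4 ranged from −0.092 to 0.61 in the ratio and −0.32 to 0.38 between fractions. ABCA3 ranged from −0.98 to 0.33 in input and −0.49 to 0.31 in RNC, and HIST2H2AA4 from −2.34 to 0.15 between fractions. OXPHOS ranged from −0.17 to 0.74 in input, and ribosomal proteins from −0.084 to 1.22 in RNC and −0.19 to 1.15 in the ratio. In the ratio NRF2 targets ranged from −2.28 to 0.08, NF-κB targets from −1.77 to 0.068 and epithelial genes from −1.27 to 0.12, and between fractions the proteasome from −0.20 to 0.42.

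With the length and GC trend removed RPS16 was at −0.056 in RNC, METTL1 at −0.21 and WDR4 at −0.043 in the ratio, and METTL1 at 0.17 and HIST1H2BK at 0.013 between fractions. With only the libraries compared RPS16 had the same value, and the KRAB list was at −0.007 with a test pointing higher. Without both shM1 libraries numbered 2 OXPHOS was at −0.17 in input, and ribosomal proteins at −0.084 and ABCA3 at 0.31 in RNC, also with only the libraries compared. Without input NC 1 and with the trend removed, 3 lists were called in the ratio and 16 between fractions. ABCA3 was then at 0.47 in input, the KRAB list at −0.007 and RPS16 at −0.056 in RNC, and METTL1 at 0.096 and HIST1H2BK at 0.48 between fractions. In the ratio the ribosomal protein list was at 0.067 with a test pointing lower, NRF2 targets at −0.009 with a test pointing higher, NF-κB targets at 0.11, METTL1 at −0.13, WDR4 at −0.12, RPS15 at −0.29, MVD at −0.31, FDPS at −0.24, NDUFS7 at −0.22, ATP5ME at −0.024, MRPL41 at −0.28 and PSMD4 at −0.082.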

Other observations

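The genes shared by the fits to single fractions and the test on G1/S genes were chosen after the results were seen.

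The fits to single fractions shared 25 genes that passed as higher and 1 that passed as lower. The RNC fit gave every gene the common trend spread, so its p-values ignore each gene's own replicate spread. LCN2, lipocalin 2, which binds bacterial siderophores, was at 0.68 and 141 TPM in input NC, 813 and 3250 TPM in input shM1, 231 and 192 TPM in RNC NC, and 1780 and 5190 TPM in RNC shM1 (limma adjusted p = 0.0207 in input and 1.39e-21 in RNC). AGR2, a disulfide isomerase of mucus-secreting cells, went from 0.81 and 179 TPM to 1670 and 1310 TPM in input and from 405 and 310 TPM to 2350 and 2000 TPM in RNC (limma adjusted p = 0.0222 and 1.89e-09). SLPI, a protease inhibitor, was at 99 and 88.1 TPM in RNC NC and 457 and 916 TPM in RNC shM1, and GPX2, a glutathione peroxidase, at 663 and 589 TPM and then 2940 and 2600 TPM. S100P, PIP and the gel-forming mucin MUC5B also passed in both. Of the 25 higher genes, 24 had every shM1 library above every NC library of the same fraction, the exception being CA9, and 23 had all 4 shM1 libraries above all 4 NC libraries. The genes were chosen from these libraries for being higher in both fits, so this separation follows largely from the choice and is not added support. CCN1, a matrix-associated growth regulator, passed as lower in both, at 239 and 34.2 TPM in input NC and 6.6 and 5.24 TPM in input shM1. Of these 26 genes, 24 were called in RNC alone with length and GC trends removed, 17 without the shM1 library numbered 2, and 5 after median-of-ratios scaling (MUC5B, APOH, CCL20, USH1C and AL163636.2, which overlaps RNASE4). In input alone 4 were called without input NC 1 (LCN2, PIP, APOH and FGL1) and none after scaling.

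A hypothesis on codons was that mRNAs rich in AGA, read by the m7G-modified arginine tRNA with anticodon TCT, lose RNC signal relative to input after knockdown. Across 11898 genes, which are not independent replicates, the partial rank correlation of AGA frequency with the change was −0.004, ranking 26 of 61 codons from the lowest. It was 0.005 without input NC 1, ranking 33. The prediction, a negative value among the lowest-ranked codons with and without input NC 1, was not met. The values near 0 thus gave no support to the hypothesis. They also did not meet the rule set for rejecting it, which needed 0 or above in both. A second hypothesis was that G1/S cyclin and CDK mRNAs lose RNC signal relative to input. Their median change was −0.013 relative to all genes and −0.085 without input NC 1, and neither passed in camera.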
